A study of Mus musculus with 8 samples.

How the data were processed

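Total RNA of mouse colon tissue was measured on 8 Illumina bead arrays. The sample titles put 2 arrays in each of 4 groups: WT, DSS, DSS+AV and DSS+Ta. The arrays titled WT were taken as the untreated control. AV and Ta were read as the antiviral and the TLR3 and TLR7 agonists of the design text, which lists the groups in the same order. The description fields differ from the titles for the DSS and DSS+AV groups, so all 6 pairwise contrasts were computed. RNA extraction, amplification and Cy3 labelling were done by the authors with kits named in the labels. Dose, duration, the compound behind AV, strain, sex, animal numbers and the chip that held each array are not given in the sources used here.

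The deposited signal table holds 25697 probes, each with a bead-averaged intensity per array that the authors had exported from GenomeStudio (version not given) without normalization between arrays. Beside each signal column stands, per the file headers, a detection p-value of that probe against negative control beads. No columns belong to samples outside the series (0 columns). Median intensity ran from 132 to 149 over the arrays. Between 11505 probes (44.8%) and 12815 probes (49.9%) had a detection p under 0.05. The deposited series value table is on the log2 scale by its values and has the same quantiles on every array (median 7.14). Its order of probes matches the signal of each array, except that the second DSS+AV column repeats the first on all 25697 probes; the normalization steps behind it are not given in the sources used here. The signal table was therefore used, and the value table, with DSS+AV represented by 1 column, served as an alternative.

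The probe annotation gave 1 gene symbol for 23978 probes and none for 1719, with 0 probes holding several. The named probes covered 16590 genes. Symbols were brought up to date through Entrez identifiers for 23962 probes, through transcript accessions for 9, and kept as annotated for 7. Signals were background corrected with limma's neqc (normexp from the detection p-values, offset 16), quantile normalised and put on the log2 scale; control probes used numbered 0. Probes with a detection p under 0.05 on both arrays of at least 1 group were kept (12398 named probes). Each gene was represented by its kept probe with the highest mean over the 8 arrays, which gave 9427 tested genes, 2234 of them with 2 or more kept probes. Probes with no symbol were left out of the comparisons.

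A means model of the 4 groups was fitted in limma 3.58.1 under R 4.3.3 with lmFit, contrasts and eBayes. The fit had 4 residual degrees of freedom and 3.35 prior degrees of freedom. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over the 9427 genes of a contrast; all tests were two-sided. An exact permutation test of 2 arrays against 2 cannot give a p under 0.333 and was not used. Log2 differences are the first group minus the second, and errors are SE from limma. Where both arrays of a group were not detected for a gene, the fold is a lower bound against the lowest log2 value among detected probes on that group's arrays (5.37 to 5.74 over the 8 arrays).

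Of 35 gene lists, 32 had at least 5 tested genes. They covered interferon-stimulated genes, the TLR3 and TLR7 pathway, interferon-gamma response and MHC class I, MHC class II, inflammatory cytokines, chemokines, leukocyte types, epithelial cell types, fetal-like and wound epithelium, antimicrobial defence, tight junction and adhesion, cell cycle, smooth muscle, extracellular matrix, endothelium, enteric neurons and glia, adipocytes, squamous epithelium, small intestine and pancreas, immediate early genes, unfolded protein response and 3 metabolic groups. The lists of mast cell and eosinophil markers (4 tested genes), red blood cells (3) and immunoglobulin transcripts (0) were too short to test. Lists were tested with camera at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 32 lists of a contrast, and again with a correlation estimated per list and with fry. Fry asks whether the genes of a list move, on balance, one way, and makes no comparison with other genes.

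Groups, contrasts, filters, tests, gene lists, the alternatives other than those named next, and the rule for naming genes were fixed before the data were examined. Chosen after seeing the data were the mean of a gene's kept probes in place of its brightest, a fit without the second DSS+AV and second DSS+Ta arrays, and the correlation of differences under each alternative. The rule for naming genes took, per contrast, the 8 highest and 8 lowest differences among genes that passed and whose arrays did not overlap. It added up to 4 members with the smallest p of every list that passed camera, up to 4 members of the interferon-stimulated, TLR3 and TLR7, cytokine and neutrophil lists in every contrast, and, where measured, Tlr3, Tlr7, Ifnb1, Isg15, Cxcl10, Lcn2, S100a8, Il1b, Il6, Tnf, Reg3g and Slc26a3. The text names part of these. Further alternatives covered background correction, normalization between arrays, detection filters, probes per gene, samples in the fit, the variance model, the replicate number as a block, and leaving out each array. The filter for probes detected on all 8 arrays used a detection p under 0.01. Because DSS+AV and DSS+Ta share the DSS arrays as reference, the correlation and covariance of their differences across genes were set against 100 simulated sets. These were unchanged groups with the same spread, in which genes varied independently.

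The procedure was tested on simulated data with the spread of each gene and 50 changed genes per size. Genes moved by 1 on the log2 scale were recovered at 66% to 78% over the 6 contrasts, genes moved by 2 at 96% to 100%, and genes moved by 0.5 at 0% to 6%; 6 to 17 unchanged genes were called per contrast. A list of 20 genes moved by 1 was found by camera in 6 of 6 contrasts, and 0 of 180 other lists were called. The simulated genes varied independently, while the correlation estimated in the data was 0.688 for the T and NK cell markers. The simulation therefore cannot show how often camera calls unchanged lists of correlated genes. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.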

Results

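Gene expression in mouse colon was measured on 8 arrays of 25697 probes, 2 for each of 4 groups. Control mice had no treatment. The other mice received dextran sulfate sodium (DSS), a polysaccharide given in drinking water that injures the colon lining and brings on colitis. DSS was given alone, with an antiviral treatment (DSS+AV), or with agonists of the receptors TLR3 and TLR7 (DSS+Ta). TLR3 and TLR7 are innate immune receptors that sense double-stranded and single-stranded RNA in endosomes, and the series set out to profile the colon with their signals withdrawn or switched on. Groups follow the sample titles. The description fields read otherwise for 2 of the groups: arrays titled DSS are described as TLR3 and TLR7 activation, and arrays titled DSS+AV as DSS treatment. The control arrays are titled WT, and no conflict was found between title and description for these or for the DSS+Ta arrays. All 6 pairwise comparisons are given. Between 11505 probes (44.8%, first DSS+AV array) and 12815 probes (49.9%, first DSS+Ta array) were detected per array. The number of arrays limits the precision. The labels do not say that the arrays of a group came from separate animals, so the p-values measure only the spread between these arrays.

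The first principal component of the 9427 tested genes held 73.8% of the variance and ordered the arrays by group. Controls lay at -58.4 and -62.4, DSS+Ta at -34.7 and 4.50, DSS at 18.6 and 24.6, and DSS+AV at 51.6 and 56.0. The SD of the log2 difference between the arrays of a group was 0.27 in control, 0.34 in DSS, 0.41 in DSS+AV and 0.53 in DSS+Ta. Every gene past the threshold in each comparison had both arrays of one group above both of the other, an order that held for 57.5% to 82.7% of all tested genes where chance gives 33.3%. Transcripts of pancreatic enzymes were high on 4 arrays: Cela2a, an elastase, measured 14.25 and 12.93 on the DSS arrays, 13.66 on the second DSS+AV array and 14.35 on the second DSS+Ta array, against 5.44 to 6.09 on the other arrays. Eif2s3y, a Y-linked gene, measured 6.73 and 6.91 on the controls and 4.61 to 4.83 elsewhere, while an Xist probe measured 5.10 and 4.83 on the controls and 6.45 to 7.23 elsewhere. Uty, also Y-linked, measured 5.99 to 6.51 and was detected on all 8 arrays. A difference in sex between the controls and the other arrays was not tested. In the comparisons against control it cannot be told apart from treatment. Probes of the same gene also moved apart between groups, on a component of within-gene differences (88.0% of their variance) that placed controls at -15.98 and -17.37, DSS+Ta at -12.48 and 0.75, DSS at 3.36 and 5.34, and DSS+AV at 19.10 and 17.28. The groups lay in the same order on this component as on the first principal component. That order and the counts of genes below may therefore follow this probe effect as well as treatment, which were not separated.

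**Figure D1:**
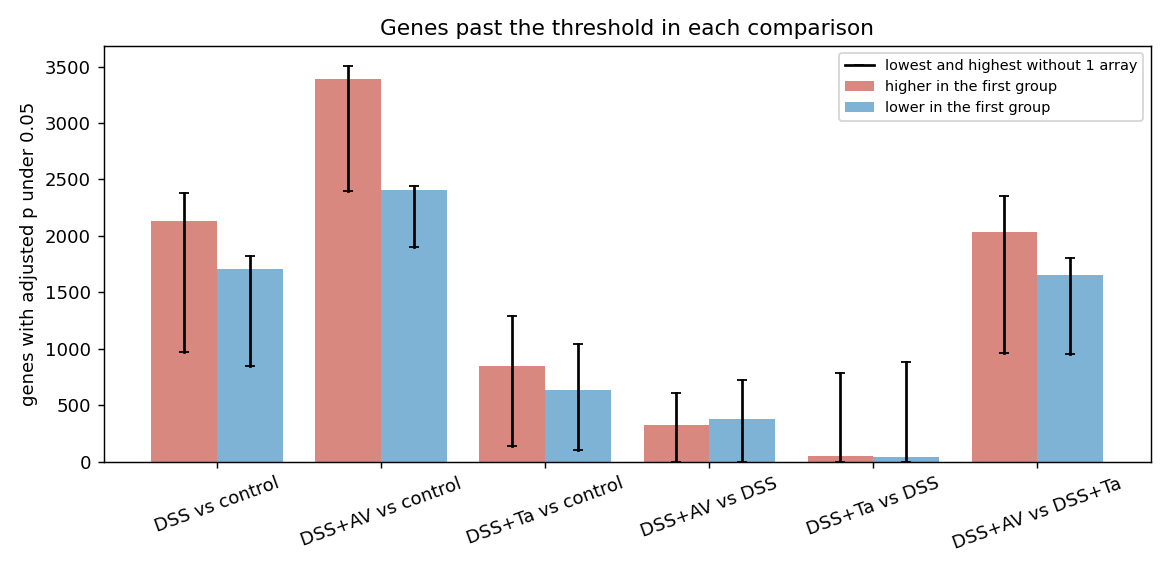
Number of genes with an adjusted p under 0.05 in each comparison, higher (red) and lower (blue) in the first group, with lines from the lowest to the highest count when 1 of the 8 arrays was left out. Counts were largest for DSS+AV against control (3388 higher, 2405 lower) and smallest for DSS+Ta against DSS (49 higher, 43 lower).

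DSS against control asks how colon exposed to DSS, by the titles, differed from untreated colon. Genes of neutrophils, cytokines, chemokines and tissue remodelling rose with DSS (2 arrays against 2). S100a8, a subunit of the neutrophil protein calprotectin, rose by 6.50 on the log2 scale (SE 0.96, adjusted p = 0.00329, limma with Benjamini-Hochberg adjustment), at least 58.3-fold since control lay below background. Il1b, a fever-inducing cytokine, rose by 5.02 (SE 0.78, adjusted p = 0.00378), and Timp1, an inhibitor of metalloproteinases, by 4.45 (SE 0.42, adjusted p = 0.00151). Reg3b, an antimicrobial lectin, rose at least 1030-fold on its brightest probe (log2 10.52, SE 0.80, adjusted p = 0.00131) and by 3.04 on its other probe. In all, 2128 genes were higher and 1711 lower, and with cyclic loess in place of quantile normalization 1692 were higher and 1990 lower.

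Among lists of genes fixed in advance, 14 of 32 passed camera, 13 upward and 1 downward. Of 22 fibroblast and extracellular matrix genes, 18 rose and 0 fell (19 and 1 adjusted over the list alone), with a median of 1.40. Timp1, Mmp2, a gelatinase, and the collagen genes Col3a1 and Col5a1 had the smallest p. The list gave adjusted p = 2.05e-06 by camera and adjusted p = 0.627 with an estimated correlation. Of 16 neutrophil markers, 12 rose (13 adjusted over the list alone), with a median of 2.02, or 1.56 with genes below background at their bound. Camera gave adjusted p = 0.000208, and adjusted p = 0.627 with an estimated correlation. Retnlg, a resistin-like protein of neutrophils, rose at least 10.4-fold, and Fpr2, a formyl peptide receptor, by 2.40. Of 12 cytokines, 10 rose (10 adjusted over the list alone), median 1.80 or 1.52 at the bounds, among them Tnf, at least 8.78-fold, Osm, at least 18.5-fold, and Il1a, at least 7.88-fold. Of 20 chemokines, 11 rose and 1 fell (12 and 1 adjusted over the list alone), median 1.16 or 1.05 at the bounds. Ccl4, which attracts macrophages, rose at least 64.2-fold. Camera gave the cytokines adjusted p = 0.000683 and the chemokines adjusted p = 0.00211, both adjusted p = 0.627 with an estimated correlation.

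Antimicrobial and epithelial defence genes rose in 11 of 20 cases and fell in 3 (12 and 3 adjusted over the list alone, median 2.34, or 2.21 at the bounds). Lcn2, which binds bacterial siderophores, rose by 3.06 (SE 0.35, adjusted p = 0.00207), Saa3, an acute-phase protein, by 5.34, and Wfdc12 by 6.60. Camera gave adjusted p = 0.0248, and adjusted p = 0.627 with an estimated correlation. Cell cycle genes rose in 12 of 21 cases and fell in 1 (the same counts adjusted over the list alone, median 0.73, or 0.64 at the bounds, adjusted p = 0.00863, and adjusted p = 0.637 with an estimated correlation). They included the replicative helicase subunits Mcm4, Mcm5 and Mcm6, which rose by 1.66, 1.54 and 1.68. Enteric neuron and glia genes rose in 6 of 8 cases (6 adjusted over the list alone, median 0.83), led by Tac1, the precursor of substance P, at 2.23. Squamous epithelium genes rose in 4 of 6 cases (6 adjusted over the list alone, median 1.06). Fetal-like and wound epithelium genes rose in 6 of 13 cases (6 adjusted over the list alone, median 0.69). Immediate early genes rose in 10 of 16 cases and fell in 2 (11 and 2 adjusted over the list alone, median 0.71), with Socs3, a brake on cytokine signalling, at 4.57. These 4 lists had camera adjusted p = 0.00945, 0.0166, 0.0475 and 0.0464, and each adjusted p = 0.627 with an estimated correlation.

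Of 29 interferon-stimulated genes, 11 rose and 0 fell with DSS (9 and 0 adjusted over the list alone, median 0.72), among them Ifitm3, a membrane protein that restricts virus entry, at 1.43 and Ifit2 at 2.75. Isg15 differed by 1.48 (SE 0.56, adjusted p = 0.0712) and Cxcl10 by 2.45 (SE 0.96, adjusted p = 0.0772), and neither passed. Interferon-gamma response and MHC class I genes rose in 9 of 19 cases and fell in 1 (12 and 1 adjusted over the list alone, median 0.83), and T and NK cell markers rose in 4 of 14 (0 adjusted over the list alone, median 0.75, or 0.69 at the bounds). The mean of the T and NK list lay 0.26 above the controls on the first DSS array and 1.24 on the second, and the 4 genes were Zap70, Il7r, Klrd1 and Icos. The interferon-stimulated, interferon-gamma and T and NK lists had camera adjusted p = 0.00595, 0.0286 and 0.0464, and each adjusted p = 0.741 with an estimated correlation. Fatty acid oxidation and ketogenesis genes fell in 4 of 14 cases and rose in 1 (8 and 1 adjusted over the list alone, median -0.44, adjusted p = 0.00595, and adjusted p = 0.627 with an estimated correlation). Ppargc1a, a coactivator of mitochondrial biogenesis, fell by 3.29, and Acadvl, an acyl-CoA dehydrogenase, by 0.87. The steepest falls were in Hnrnpl, a splicing regulator (fell by 7.17), Ggact (at least 23.3-fold lower) and Eef2, a translation elongation factor (at least 28.5-fold lower on its brightest probe, with its 3 probes between -5.03 and -4.23). Among 143 genes with a fall of 4-fold or more on 1 probe and a second well-measured probe, 66 (46.2%, exact 95% interval 37.8 to 54.7) had another probe that fell by under 0.5 or rose. In 4 of the 143 genes the other probe was called higher. Here and below, a 4-fold change counted only where its probe passed at an adjusted p under 0.05, each probe tested as its own feature. A probe was well measured where the higher of the 2 compared group means was at least 7 on the log2 scale. Among 15 such rises, 3 (20%) had another probe that rose by under 0.5 or fell, and in 1 it was called lower.

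The count of 3839 genes fell to 2185 without the first control array, 1820 without the second, 2530 without the first DSS array and 1848 without the second, and 1432 of the genes (37.3%) passed in all 4 of these fits. Among the genes named as changed, Ifit2 did not pass without the second control array. Zap70, Il7r and Klrd1 did not pass without the first or second control array or the second DSS array, Icos passed in 0 of the 4 fits (limma), and the other named genes passed in all 4. Both DSS arrays held pancreatic transcripts, and DSS and control differed in Eif2s3y and Xist, as given above.

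**Figure D2:**
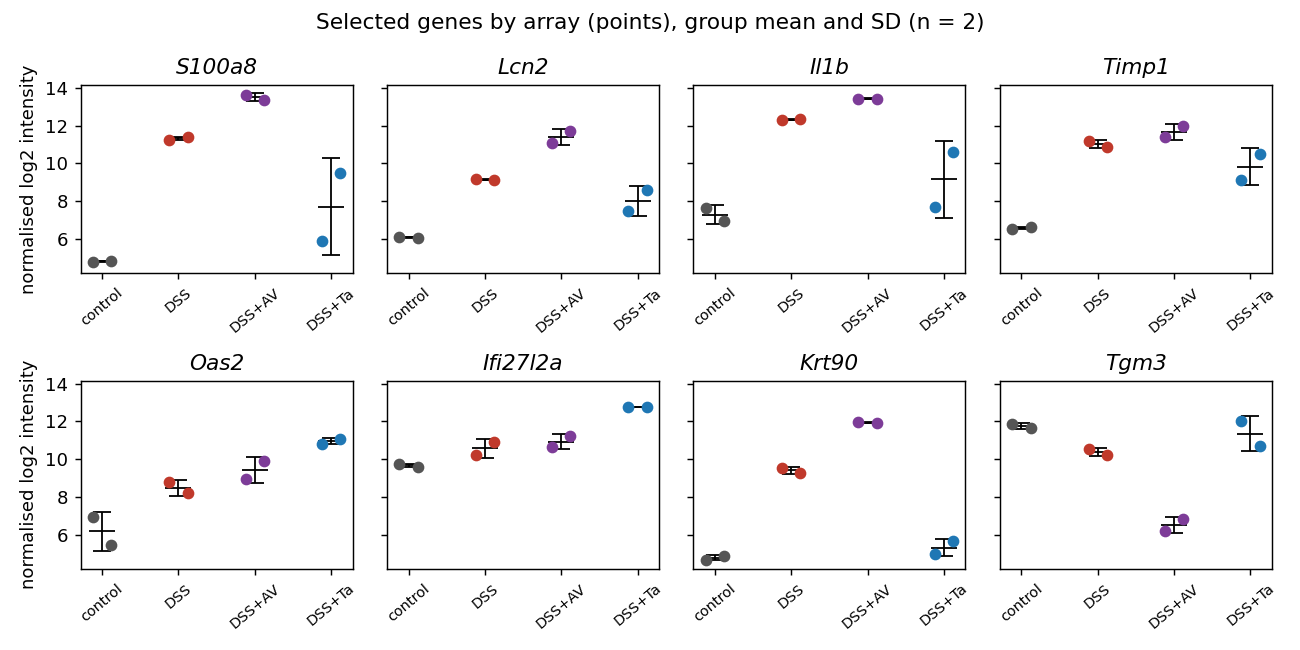
Normalised log2 intensity of 8 genes on each array (points), with the mean and SD of the 2 arrays of a group. S100a8, Lcn2, Il1b and Timp1 were higher in DSS and DSS+AV than in control, Oas2 and Ifi27l2a were highest in DSS+Ta, and Krt90 was highest and Tgm3 lowest in DSS+AV.

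DSS+AV against control asks how colon given DSS and the antiviral, by the titles, differed from untreated colon. Several inflammatory genes that rose with DSS also rose here: S100a8 rose by 8.69 (SE 0.96, adjusted p = 0.000419, at least 266-fold), Il1b by 6.12 (SE 0.78, adjusted p = 0.00067), Lcn2 by 5.32 (SE 0.35, adjusted p = 0.000202) and Reg3b at least 1170-fold on its brightest probe. Krt90, a keratin, rose at least 89.0-fold (log2 7.15, SE 0.22, adjusted p = 3.29e-05). The comparison called 3388 genes higher and 2405 lower, and 8 of 32 lists passed camera.

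Neutrophil markers rose in 14 of 16 cases and fell in 0 (14 adjusted over the list alone, median 2.995, or 2.67 at the bounds, adjusted p = 3.83e-05, and adjusted p = 0.671 with an estimated correlation). Extracellular matrix genes rose in 19 of 22 cases (19 adjusted over the list alone, median 1.70), with Lox, a collagen crosslinking enzyme, at 3.19 and Col3a1 at 2.56. Chemokines rose in 17 of 20 cases and fell in 1 (the same counts adjusted over the list alone, median 2.43, or 2.02 at the bounds), and cytokines rose in 10 of 12 (11 adjusted over the list alone, median 2.64, or 2.47 at the bounds). These 3 lists had camera adjusted p = 8.28e-06, 0.000669 and 0.0019, and each adjusted p = 0.671 with an estimated correlation. T and NK cell markers rose in 13 of 14 cases (13 adjusted over the list alone, median 1.68, adjusted p = 0.00484, and adjusted p = 0.771 with an estimated correlation), including Foxp3, the regulatory T cell factor, at 1.56 and Il7r at 1.88. Interferon-stimulated genes rose in 17 of 29 cases (17 adjusted over the list alone, median 1.13, or 1.10 at the bounds, adjusted p = 0.0194, and adjusted p = 0.787 with an estimated correlation), with Oas2, a sensor of double-stranded RNA, at 3.23. Enteric neuron and glia genes rose in 5 of 8 cases (5 adjusted over the list alone, median 1.26, adjusted p = 0.0437, and adjusted p = 0.671 with an estimated correlation), with Vip, a neuropeptide, at 2.63. Fatty acid oxidation genes fell in 7 of 14 cases and rose in 1 (the same counts adjusted over the list alone, median -0.37, adjusted p = 0.0187, and adjusted p = 0.671 with an estimated correlation). The steepest falls were in Hnrnpl (fell by 7.38), Mettl7a2 (at least 28.4-fold lower), Ggact (at least 21.5-fold lower) and Tgm3, a transglutaminase (fell by 5.23). Of 333 genes with a 4-fold fall on 1 probe, 155 (46.5%) had another probe that fell by under 0.5 or rose, and in 43 it was called higher. For rises, with the directions reversed, it was 4 of 62 (6.5%), and in 1 the other probe was called lower.

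Leaving out 1 array left between 4296 and 5938 genes, within 1.5 times the count of 5793, and 3740 genes (64.6%) passed in all 4 fits without 1 of the compared arrays. Pancreatic transcripts were on the second DSS+AV array only, and Eif2s3y and Xist differed between these groups as between DSS and control. With cyclic loess in place of quantile normalization, the median of all genes moved from 0.18 to 0.02, and 2637 genes were higher and 2816 lower.

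DSS+Ta against control asks how colon given DSS and the receptor agonists differed from untreated colon. Among interferon-stimulated genes, Oas2 rose by 4.75 (SE 0.50, adjusted p = 0.00369), Ifi27l2a by 3.10 (SE 0.27, adjusted p = 0.00276) and Bst2, which tethers budding virus to the cell, by 2.27 (SE 0.28, adjusted p = 0.00511). Reg3b rose at least 196-fold on its brightest probe, with 0.68 on its other probe, and Gpnmb, a glycoprotein of macrophages, by 3.46 (SE 0.31, adjusted p = 0.0032). S100a8, below background in control, differed by at least 4.75-fold (adjusted p = 0.0794) and Il1b by 1.86 (SE 0.78, adjusted p = 0.141), and neither passed. Lcn2 and Tnf were called higher in DSS+Ta than in control. When 1 compared array was left out, their log2 differences ran from 1.38 to 2.51 for Lcn2 and from 1.42 to 2.27 for Tnf. In all, 848 genes were higher and 632 lower, and with cyclic loess 703 were higher and 736 lower.

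Of 32 lists 18 passed camera. Interferon-stimulated genes rose in 17 of 29 cases and fell in 0 (23 and 0 adjusted over the list alone, median 1.61, or 1.54 at the bounds, adjusted p = 1.77e-09, and adjusted p = 0.439 with an estimated correlation). On single arrays the mean of this list lay 1.65 and 1.73 above the controls in DSS+Ta, 1.25 and 0.74 in DSS, and 0.81 and 1.70 in DSS+AV. Extracellular matrix genes rose in 15 of 22 cases (19 adjusted over the list alone, median 1.13, adjusted p = 2.13e-09, and adjusted p = 0.439 with an estimated correlation), including Pdgfra, a fibroblast receptor, at 1.57 and Mmp2 at 1.53. Cell cycle genes rose in 10 of 21 cases and fell in 1 (15 and 1 adjusted over the list alone, median 0.58, adjusted p = 4.7e-06, and adjusted p = 0.439 with an estimated correlation), with Mcm5 at 1.27, and endothelial genes rose in 9 of 19 (11 adjusted over the list alone, median 0.68, adjusted p = 0.000147, and adjusted p = 0.439 with an estimated correlation), with Vcam1, a leukocyte adhesion molecule, at 1.66. Monocyte and macrophage markers rose in 8 of 13 cases and fell in 1 (9 and 1 adjusted over the list alone, median 0.81, or 0.71 at the bounds, adjusted p = 0.00279, and adjusted p = 0.439 with an estimated correlation), with the complement gene C1qb at 1.36. Fatty acid oxidation genes fell in 2 of 14 cases (8 adjusted over the list alone, median -0.45, adjusted p = 0.000259, and adjusted p = 0.439 with an estimated correlation), and chemokines rose in 8 of 20 (10, with 1 fall, adjusted over the list alone, median 0.99, or 0.82 at the bounds, adjusted p = 0.00162, and adjusted p = 0.439 with an estimated correlation). Antimicrobial genes rose in 6 of 20 cases (6, with 1 fall, adjusted over the list alone, median 0.94, or 0.66 at the bounds, adjusted p = 0.0116, and adjusted p = 0.439 with an estimated correlation).

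T and NK cell markers rose in 5 of 14 cases (11 adjusted over the list alone, median 1.27, or 1.14 at the bounds, adjusted p = 0.000274), and cytokines in 3 of 12 (4 adjusted over the list alone, median 0.78, or 0.66 at the bounds, adjusted p = 0.00819); both had adjusted p = 0.444 with an estimated correlation. Neutrophil markers rose in 2 of 16 cases (4 adjusted over the list alone, median 0.52, or 0.26 at the bounds, adjusted p = 0.0165, and adjusted p = 0.447 with an estimated correlation), and their mean lay 0.43 above the controls on the first DSS+Ta array and 1.36 on the second. Interferon-gamma response and MHC class I genes rose in 3 of 19 cases (3 adjusted over the list alone, median 0.75, adjusted p = 0.00424), MHC class II genes in 0 of 11 (0 adjusted over the list alone, median 0.60, or 0.53 at the bounds, adjusted p = 0.031), and xenobiotic and steroid metabolism genes fell in 0 of 19 (0 adjusted over the list alone, median -0.32, adjusted p = 0.0125); these 3 had adjusted p = 0.499 with an estimated correlation. Colonocyte markers fell in 2 of 24 cases and rose in 1 (4 and 1 adjusted over the list alone, median -0.23, adjusted p = 0.022, and adjusted p = 0.439 with an estimated correlation), with the water channel Aqp4 at -1.30. Fetal-like epithelium genes rose in 4 of 13 cases and fell in 2 (5 and 2 adjusted over the list alone, median 0.84, adjusted p = 0.0411, and adjusted p = 0.439 with an estimated correlation), and immediate early genes rose in 5 of 16 and fell in 2 (8 and 3 adjusted over the list alone, median 0.49, adjusted p = 0.0442, and adjusted p = 0.439 with an estimated correlation). Enteroendocrine markers fell in 1 of 16 cases (1 adjusted over the list alone, median -0.25, adjusted p = 0.031, and adjusted p = 0.447 with an estimated correlation). The gene that fell there was Neurog3, the endocrine progenitor factor, by 1.46. The steepest falls held Ggact (fell by 4.90) and Arl2bp (at least 14.9-fold lower on its brightest probe, with its 3 probes between -4.31 and -0.52). Of 30 genes with a 4-fold fall on 1 probe, 17 (56.7%) had another probe that fell by under 0.5 or rose. For rises, with the directions reversed, it was 0 of 7.

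The count of 1480 genes became 259 without the first control array, 243 without the second, 2330 without the first DSS+Ta array and 586 without the second, and 163 genes passed in all 4 fits. Among the genes named as changed, C1qb, Aqp4 and Lcn2 did not pass without the first or without the second control array. Neurog3 and Tnf did not pass without any 1 of these or the second DSS+Ta array, and Vcam1 did not pass without the second control array. The first DSS+Ta array lay nearer the controls than the second in the antimicrobial (0.63 and 2.20), neutrophil, cytokine and chemokine lists. Only the second held pancreatic transcripts, and Eif2s3y and Xist differed between the groups.

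**Figure D3:**
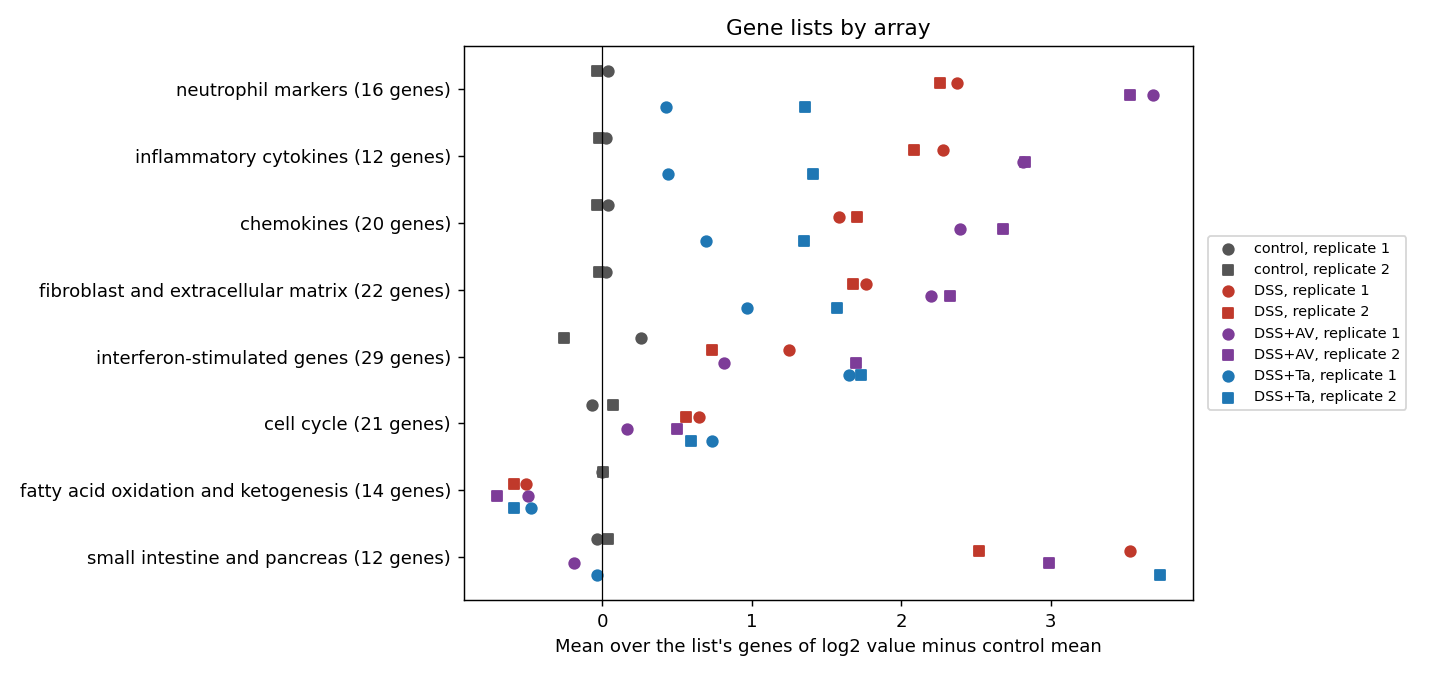
Mean over the tested genes of 8 lists, as log2 value minus the control mean, on each of the 8 arrays (colour marks the group, shape the replicate). Neutrophil markers lay at 2.38 and 2.26 in DSS, 3.69 and 3.53 in DSS+AV, and 0.43 and 1.36 in DSS+Ta, while the list with pancreatic genes was high on both DSS arrays and on the second array of DSS+AV and DSS+Ta.

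DSS+AV against DSS asks whether colon given the antiviral with DSS differed from colon given DSS, if the titles hold. Among genes of neutrophils and other myeloid cells, Lcn2 rose by 2.26 (SE 0.35, adjusted p = 0.0254), Fpr2 by 2.24 (SE 0.29, adjusted p = 0.0221), Retnlg by 2.70 (SE 0.46, adjusted p = 0.0268) and Chil3, a chitinase-like protein of macrophages, at least 3.28-fold (adjusted p = 0.0153). Il19, a cytokine of the IL-10 family, rose at least 6.12-fold (adjusted p = 0.0221), and Krt90 by 2.52 (SE 0.22, adjusted p = 0.0143). S100a8 differed by 2.19 (SE 0.96, adjusted p = 0.182), Isg15 by -0.11 (SE 0.56, adjusted p = 0.921) and Tnf by -0.09 (SE 0.34, adjusted p = 0.882), and none of the 3 passed. In all, 323 genes were higher and 382 lower. These counts were 218 and 809 with median scaling and 239 and 455 with cyclic loess.

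Of 32 lists 7 passed camera. Neutrophil markers rose in 8 of 16 cases (9 adjusted over the list alone, median 1.16, or 1.08 at the bounds, adjusted p = 6.32e-05, and adjusted p = 0.735 with an estimated correlation). Extracellular matrix genes rose in 4 of 22 cases (8 adjusted over the list alone, median 0.45), with Lox at 1.36. Chemokines rose in 3 of 20 cases (8 adjusted over the list alone, median 0.79), namely Ccl2, which recruits monocytes, at least 3.86-fold, Ccl7 by 2.07 and Cxcl5 at least 2.08-fold. T and NK cell markers rose in 2 of 14 cases (4 adjusted over the list alone, median 0.93), Foxp3 by 1.07 and Il7r by 1.23. Smooth muscle genes fell in 1 of 15 cases (9 adjusted over the list alone, median -0.58). This was Tagln, an actin-binding protein, which fell by 1.02. The last 4 lists each had camera adjusted p = 0.000484, and adjusted p = 0.735 with an estimated correlation. Endothelial genes rose in 3 of 19 cases (8, with 1 fall, adjusted over the list alone, median 0.51, adjusted p = 0.00772, and adjusted p = 0.735 with an estimated correlation), and monocyte and macrophage markers in 4 of 13 (6 adjusted over the list alone, median 0.37, adjusted p = 0.00827, and adjusted p = 0.735 with an estimated correlation), including Arg1, an arginase of activated macrophages, at 1.41 and the Fc receptor gene Fcgr1 at 1.65. Of 29 interferon-stimulated genes, 1 rose and 0 fell (1 adjusted over the list alone, median 0.33, adjusted p = 0.419); this was Ifitm3, by 0.82. The steepest falls were in Fxyd4, a regulator of the sodium pump (fell by 3.92), Tgm3 (fell by 3.87) and Eno3, an enolase (fell by 2.86). Hnrnpk fell by 2.14 on its brightest probe and differed by 0.20 on another. Of 12 genes with a 4-fold fall, 7 (58.3%) had another probe that fell by under 0.5 or rose.

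The genes named as changed kept their direction when 1 compared array was left out, with log2 differences of 2.37 to 2.64 for Krt90, 1.94 to 2.54 for Lcn2 and 1.09 to 2.39 for Cxcl5, but the calls did not hold. The count of 705 genes became 0 without the first control array (2445 genes at an unadjusted p under 0.05 in limma), 0 without the second (2456), 1 without the first DSS array, 0 without the second (2172), 12 without the first DSS+AV array, 40 without the second, 1329 without the first DSS+Ta array and 1318 without the second. Of the 705 genes, 0 passed in all 4 fits without 1 of the compared arrays, so each gene called here lost its call in at least 1 of them. Pancreatic transcripts were on both DSS arrays and on the second DSS+AV array only.

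DSS+Ta against DSS asks whether colon given the agonists with DSS differed from colon given DSS, if the titles hold. Krt90 fell by 4.09 (SE 0.22, adjusted p = 0.0019), Arg1 by 2.89 (SE 0.19, adjusted p = 0.00415), the chemokine gene Cxcl2 by 3.03 (SE 0.31, adjusted p = 0.0251) and Il1a by 2.80 (SE 0.43, adjusted p = 0.0416). Some interferon-induced genes were higher: Ifi27l2a rose by 2.20 (SE 0.27, adjusted p = 0.032), Bst2 by 1.82 (SE 0.28, adjusted p = 0.0416) and Ly6e by 2.18 (SE 0.34, adjusted p = 0.0429). Siglec1, a lectin of macrophages, rose by 2.07 (SE 0.34, adjusted p = 0.0461). S100a8 differed by -3.62 (SE 0.96, adjusted p = 0.0878) and Il1b by -3.16 (SE 0.78, adjusted p = 0.0823), and neither passed, so their calls against control do not show that DSS+Ta differed from DSS in these genes. In all, 49 genes were higher and 43 lower, with splits of 63 and 93 under median scaling, 91 and 135 under normexp with an offset, and 83 and 117 without background correction.

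Of 32 lists 8 passed camera. Neutrophil markers fell in 2 of 16 cases, Trem3 by 1.25 and Clec4e by 1.41 (10 adjusted over the list alone, median -1.39, adjusted p = 8.44e-06, and adjusted p = 0.771 with an estimated correlation). Enteroendocrine markers fell in 0 of 16 cases (7 adjusted over the list alone, median -0.42, adjusted p = 0.000135, and adjusted p = 0.771 with an estimated correlation), enteric neuron and glia genes in 1 of 8 (3 adjusted over the list alone, median -0.36, adjusted p = 0.00364, and adjusted p = 0.771 with an estimated correlation), which was Tac1, by 1.85, and squamous epithelium genes in 0 of 6 (5 adjusted over the list alone, median -0.64, adjusted p = 0.00836, and adjusted p = 0.771 with an estimated correlation). Interferon-stimulated genes rose in 2 of 29 cases (6 adjusted over the list alone, median 0.60, adjusted p = 0.000148, and adjusted p = 0.868 with an estimated correlation), and cytokines fell in 1 of 12 (6 adjusted over the list alone, median -0.85, adjusted p = 0.00169, and adjusted p = 0.868 with an estimated correlation). Endothelial genes rose in 0 of 19 cases (2 adjusted over the list alone, median 0.32, adjusted p = 0.0168, and adjusted p = 0.868 with an estimated correlation), and monocyte and macrophage markers rose in 1 of 13 and fell in 1 (8 and 2 adjusted over the list alone, median 0.54, adjusted p = 0.0412, and adjusted p = 0.868 with an estimated correlation), C1qb by 1.26 upward and Arg1 downward. No gene had a 4-fold fall that passed the threshold on 1 of several well-measured probes in this comparison (0 genes). Falls that did not pass were not counted.

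The count of 92 genes became 3 without the first control array, 4 without the second, 1 without either the first or the second DSS array, 25 without the first or the second DSS+AV array, 6 without the first DSS+Ta array and 1676 without the second. It was 0 in a fit of these 2 groups alone (1840 genes at an unadjusted p under 0.05 in limma), and of the 92 genes 1, Krt90, passed in all 4 fits without 1 of the compared arrays. The others named as changed did not pass without either DSS array, and all of these but Arg1 and Tac1 also did not pass without the first DSS+Ta array. Pancreatic transcripts were on both DSS arrays and on the second DSS+Ta array only, and without that array and the second DSS+AV array 1652 genes passed.

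DSS+AV against DSS+Ta sets withdrawal and activation side by side, if the titles hold. Neutrophil and cytokine genes were higher on the arrays titled DSS+AV: S100a8 by 5.80 (SE 0.96, adjusted p = 0.00488), Il1b by 4.25 (SE 0.78, adjusted p = 0.00671), Lcn2 by 3.37 (SE 0.35, adjusted p = 0.002) and Krt90 by 6.60 (SE 0.22, adjusted p = 5.84e-05). Of 29 interferon-stimulated genes 8 were lower, though the list did not pass, with Oas3 at -2.13 (SE 0.36, adjusted p = 0.00511), Irf7, the transcription factor that amplifies interferon production, at -1.88 (SE 0.35, adjusted p = 0.00673) and Ifi27l2a at -1.85 (SE 0.27, adjusted p = 0.0035). In all, 2038 genes were higher and 1655 lower. The split was 1562 and 1928 with median scaling and 1560 and 1901 with cyclic loess.

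Of 32 lists 5 passed camera, all upward. Neutrophil markers rose in 14 of 16 cases (14 adjusted over the list alone, median 2.51, adjusted p = 3.64e-06, and adjusted p = 0.916 with an estimated correlation), with Fpr2 at 3.60. Cytokines rose in 9 of 12 cases (10 adjusted over the list alone, median 1.37), with Il11 at 3.25, chemokines rose in 12 of 20 and fell in 1 (12 and 2 adjusted over the list alone, median 1.15), and extracellular matrix genes rose in 11 of 22 and fell in 1 (12 and 1 adjusted over the list alone, median 0.64), with Inhba, an activin subunit, at 2.96. The last 3 lists each had camera adjusted p = 0.00648, and adjusted p = 0.916 with an estimated correlation. Enteric neuron and glia genes rose in 6 of 8 cases (6 adjusted over the list alone, median 0.72, adjusted p = 0.0268, and adjusted p = 0.916 with an estimated correlation), with the receptor gene Ret at 1.78. Interferon-stimulated genes fell in 8 of 29 cases and rose in 1 (7 and 1 adjusted over the list alone, median -0.48), and the list did not pass (adjusted p = 0.121). The steepest falls were in Tgm3 (fell by 4.83), Mettl7a2 (at least 16.6-fold lower) and Casp14, a caspase of cornifying epithelium (fell by 3.88). Hnrnpk fell by 3.80 on its brightest probe and differed by 0.23 on another. Of 129 genes with a 4-fold fall, 62 (48.1%) had another probe that fell by under 0.5 or rose, and in 7 it was called higher. For rises, with the directions reversed, it was 0 of 13.

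The count of 3693 genes became 1998 without the first DSS+AV array, 2413 without the second, 1919 without the first DSS+Ta array and 2452 in a fit of these 2 groups alone. Of the called genes, 1534 genes (41.5%) passed in all 4 fits without 1 of the compared arrays, including each gene named as changed. Pancreatic transcripts were on the second array of each group.

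**Figure D4:**
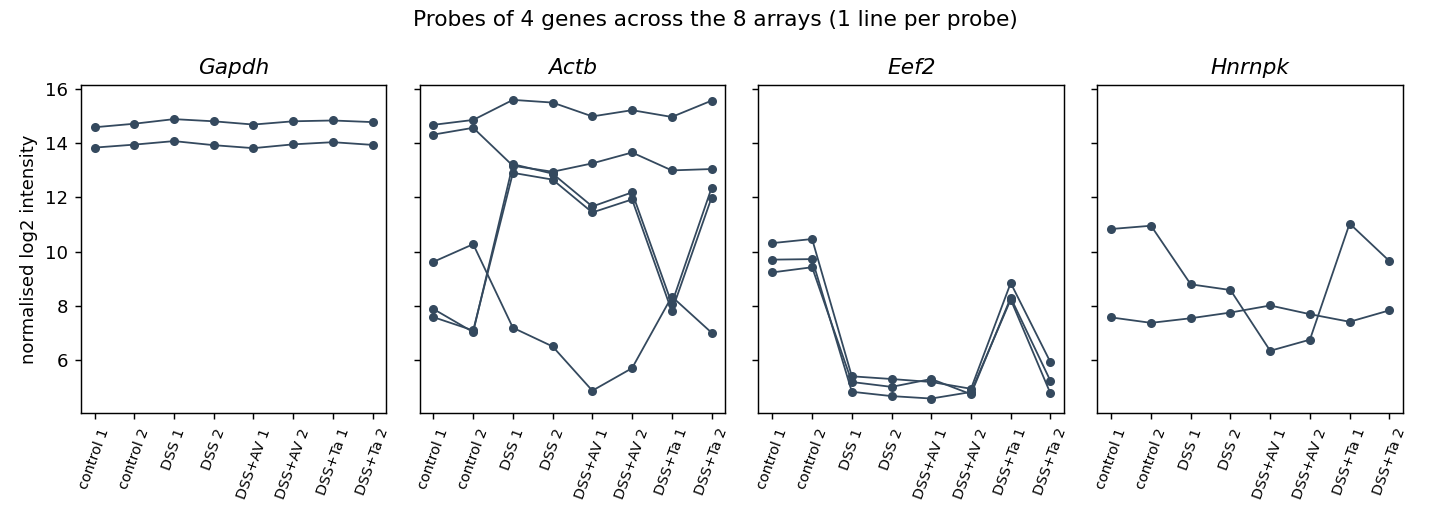
Normalised log2 intensity of each probe detected on at least 1 array (1 line per probe) of Gapdh, Actb, Eef2 and Hnrnpk on the 8 arrays. These genes were chosen after their values were seen. The Eef2 probes were detected on 4, 3 and 3 of the 8 arrays. One Actb probe measured 7.88 and 7.03 on the controls and 13.22 and 12.87 on the DSS arrays. Another Actb probe measured 9.62 and 10.27 on the controls and 7.19 and 6.50 on the DSS arrays. One Hnrnpk probe fell from 10.83 and 10.95 on the controls to 6.34 and 6.75 on the DSS+AV arrays while the other stayed between 7.37 and 8.01.

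Tlr7 rose by 1.11 with DSS (SE 0.24, adjusted p = 0.0107), by 1.91 with DSS+AV (SE 0.24, adjusted p = 0.000615) and by 1.16 with DSS+Ta (SE 0.24, adjusted p = 0.0215), each against control. It differed by 0.81 between DSS+AV and DSS (SE 0.24, adjusted p = 0.0819) and by 0.06 between DSS+Ta and DSS (SE 0.24, adjusted p = 0.907), and neither passed. Tlr7 was higher by 0.75 in DSS+AV than in DSS+Ta (SE 0.24, adjusted p = 0.042), a call that did not pass without any 1 of these 4 arrays. The DSS call of Tlr7 did not pass without the second control or the second DSS array, and its DSS+Ta call did not pass without either control array or the second DSS+Ta array. Probes for Tlr3, Ifnb1 and Il6 were detected on 0 of 8 arrays, which leaves these transcripts unmeasured here. The TLR3 and TLR7 pathway list of 16 genes did not pass camera in any comparison, with its lowest adjusted p = 0.0682 in DSS+Ta against control, where 4 genes rose and 0 fell (5 adjusted over the list alone, median 0.37).

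Across the 9427 genes, the DSS+AV minus DSS differences and the DSS+Ta minus DSS differences had a Pearson r of -0.30. Because both use the same DSS arrays, unchanged groups with independent genes would give a positive value: the mean of 100 simulated sets was 0.50 (0.41 to 0.59). Deviations of the real replicates correlated between groups at -0.322 to 0.353, so this range is likely too narrow. DSS also lay between DSS+Ta and DSS+AV on the within-gene probe component. Whether that order gives the negative r was not tested. The covariance was -0.08 against a simulated 0.03. Without the second DSS array r was -0.09 and without the first DSS+Ta array it was -0.19. Genes are not independent replicates, so no p-value was attached.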

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

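The count of unnamed probes was made only after the comparisons of named genes had been seen. The probe annotation gave no gene symbol for 1719 probes, which the comparisons left out, and 744 of these passed the detection filter. Of the 744 probes, 143 were higher in DSS than in control at an adjusted p under 0.05 and 160 were lower. Between DSS+AV and control 245 were higher and 232 lower, and between DSS+Ta and control 72 were higher and 57 lower. The largest rise in DSS was 7.45 on the log2 scale. Which transcripts these probes measure was not examined, and no explanation was tested.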

How the results depend on the processing

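With 2 arrays per group, each comparison rested on 4 arrays plus the spread of the other groups, and counts moved most where groups were close. Over named genes, 378 results met 6242 alternatives: 5513 gave the same call, 693 were weaker, 34 stronger and 2 reversed. Of 1020 alternatives for list medians, 814 stayed the same, 206 moved and 0 reversed. The reversals were Hnrnpk in DSS+AV against DSS (0.203) and against DSS+Ta (0.229) when only probes with a detection p under 0.01 on all 8 arrays were kept. Another probe of the gene stood for it there. For causes other than this one, the cause was not tested. A limit of the signal table is that bead spread was not used here, and lower bounds rest on the detection p-values.

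Leaving out 1 array gave 1820 to 4189 genes for DSS against control, 243 to 2330 for DSS+Ta against control, 0 to 1329 for DSS+AV against DSS, 1 to 1676 for DSS+Ta against DSS and 1919 to 4158 for DSS+AV against DSS+Ta. In these fits the lone array of a group was assumed to vary like the other groups.

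For DSS+Ta against DSS, where 92 genes passed, the count was 226 with normexp and an offset of 50, 200 without background correction, 156 with median scaling, 41 from the value table, 43 without a detection filter, 180 with probes detected on all 8 arrays, 42 with each probe its own feature and 336 with a trended robust variance. A fit of only the compared groups gave 0 genes (1840 at an unadjusted p under 0.05 in limma). DSS+AV against DSS gave 19 from the value table, in which DSS+AV had 1 column. Fits of only the compared groups gave 721 for DSS+Ta against control and 2452 for DSS+AV against DSS+Ta. Leaving out the second DSS+AV and DSS+Ta arrays together, chosen after pancreatic transcripts were seen, gave 513 for DSS+Ta against control and 1652 for DSS+Ta against DSS. The mean of a gene's probes, also chosen after the data were seen, gave 3988, 5875, 1589, 730, 80 and 3808 in the 6 comparisons, near the counts with the brightest probe. Scaling moved the median of all genes from 0.124 to 0.021 for DSS against control with cyclic loess and from 0.051 to -0.068 for DSS+AV against DSS with median scaling.

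With the replicate number as a replicate block, 421 genes passed for DSS+AV against DSS and 20 for DSS+Ta against DSS, and the other comparisons gave 3567, 5551, 1312 and 3402. The replicate numbers did not pair, as deviations from group means correlated between groups at -0.322 to 0.353. The chip of each array was not used here, so no chip block was fitted.

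With a correlation estimated per list, 0 lists passed camera in any of the 6 comparisons, and 1, 0, 1, 0, 0 and 0 had an unadjusted p under 0.05. Fry called 15, 20, 14, 0, 0 and 7 lists against 14, 8, 18, 7, 8 and 5 for camera, and in DSS+AV and DSS+Ta against DSS, where fry called 0, its unadjusted p was under 0.05 for 8 and 5 lists.

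The correlation between DSS+AV minus DSS and DSS+Ta minus DSS, whose alternatives were added after it was seen, was -0.257 with the value table, -0.256 without a detection filter, -0.348 with probes detected on all 8 arrays or with each probe its own feature, and -0.203 without the pancreas-positive DSS+AV and DSS+Ta arrays. It ran from -0.329 to -0.085 without 1 array and was negative throughout.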

Other observations

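The genes of this paragraph were chosen after their values were seen, and each value is against control by limma. Colonocyte markers, the list that holds Aqp8 and Hsd11b2, rose in 5 of 24 cases and fell in 6 with DSS. Their median was -0.043 (camera adjusted p = 0.339). With DSS+AV 5 rose and 8 fell, with a median of -0.045 (camera adjusted p = 0.224). The list passed in neither comparison. Aqp8, a water channel of colonocytes, fell by 1.54 with DSS (SE 0.28, adjusted p = 0.00582) and by 3.31 with DSS+AV (adjusted p = 0.000229), and differed by -0.62 with DSS+Ta (adjusted p = 0.166), which did not pass. Hsd11b2, which inactivates glucocorticoids, fell by 3.40 with DSS and by 1.90 with DSS+Ta, and the DSS+Ta call did not pass without the first or second control array or the second DSS+Ta array. Of the junction genes, whose list did not pass, Cldn4 fell by 1.92 with DSS and 2.14 with DSS+AV, and Ocln by 1.19 with DSS. Lrig1, a stem cell marker, fell by 1.54 with DSS and 2.23 with DSS+AV. Lgr5, another, was at least 1.28-fold lower with DSS, a call that did not pass without the first control or the second DSS array. Creb3l1, a secretory pathway factor, fell by 1.97 with DSS and 2.91 with DSS+AV. The goblet cell channel Best2 fell by 2.08 with DSS, while Retnlb, a goblet cell product induced in colitis, rose by 2.29, a call that did not pass without either DSS array. Slc51b, a bile acid exporter subunit, rose by 1.86 with DSS and 1.85 with DSS+AV.

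Several lists passed camera in none of the 6 comparisons. In DSS against control, stem and progenitor markers rose in 1 of 10 cases and fell in 5 (adjusted p = 0.256), tight junction genes rose in 2 of 17 and fell in 5 (adjusted p = 0.251), and unfolded protein response genes rose in 8 of 15 and fell in 3 (adjusted p = 0.201). Goblet cell markers rose in 2 of 15 cases and fell in 2 (adjusted p = 0.499), tuft cell markers rose in 1 of 7 (adjusted p = 0.15), and adipocyte genes rose in 3 of 11 (adjusted p = 0.386). Dendritic cell markers rose in 1 of 8 cases and fell in 1 (adjusted p = 0.795), and respiratory chain genes changed in 0 of 30 (adjusted p = 0.794). B and plasma cell markers fell in 1 of 14 cases (adjusted p = 0.918), with array means of -0.44 and 1.05 in DSS. The list of small intestine and pancreas genes changed in 0 of 12 cases, with a median of 2.88 (adjusted p = 0.339). Median, mean and camera direction differed in sign for 3, 4, 2, 2, 3 and 6 lists in the 6 comparisons, none of which passed.

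All tests that follow were chosen after results were seen, except the test of neutrophil markers on the arrays titled DSS. Pancreatic enzyme transcripts were high on both DSS arrays and on the second DSS+AV and DSS+Ta arrays. If pancreatic tissue was in those extracts, further pancreatic genes should follow, and their median was higher on the second than on the first array by at least 2.88 in DSS+AV and DSS+Ta. Of these 21 genes, 11 in DSS+AV and 13 in DSS+Ta were higher by at least 2. Their lower quartiles were -0.12 and 0.78. An effect shared by the arrays of a group would not separate them, yet the enzyme transcripts of the fixed list differed by 4.57 between the DSS+AV arrays and 5.80 between the DSS+Ta arrays, with lower quartiles of 2.38 and 2.88. This argues against a shared effect, while an effect in some animals alone was not tested. Small intestine genes differed by -0.07 in DSS+AV and -0.40 in DSS+Ta, but 3 of 12 were detected and their control median of 8.88 would hide a small share of such RNA, so that stays open too. Pancreatic tissue taken with the colon could account for the transcripts.

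Many steep falls were seen on 1 probe of a gene and not on another. Lower expression of whole genes would lower both probes. Yet 46.2% of genes with a 4-fold fall in DSS had another probe that fell by under 0.5 or rose (exact 95% interval 37.8 to 54.7). For rises, with the directions reversed, it was 3 of 15 (4.3 to 48.1), which overlaps. In DSS+AV it was 4 of 62 rises (1.8 to 15.7) against 155 of 333 falls (41.1 to 52.1). These intervals take genes as independent although they were measured on the same arrays, so they do not measure the spread between arrays. Pancreatic ribonucleases in the extract would spare arrays without pancreatic transcripts, but the first DSS+AV array lay highest on the within-gene component, at 19.10, which argues against them as the only cause, while the DSS+Ta arrays lay at -12.48 without and 0.75 with these transcripts. Loss of parts of transcripts in RNA or cDNA might separate arrays of a group, and the DSS+Ta arrays lay 13.23 apart against 1.39 for the controls, which does not tell it from a difference in treatment response. Other transcript ends remain possible, as probe positions were not used here.

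The descriptions give the arrays titled DSS as receptor activation and those titled DSS+AV as DSS treatment. If the arrays titled DSS had received agonists without DSS, neutrophil markers were predicted not to pass upward, and their median rose by 2.02 (adjusted p = 0.000208, and adjusted p = 0.627 with an estimated correlation). If the first DSS+Ta array, which lay nearest the controls, were a control sample, its interferon-stimulated genes would lie near theirs, and their mean was 1.65 higher where the controls lay 0.26 from their own mean. The neutrophil markers cannot decide between titles and descriptions, since whether agonists without DSS raise them was not measured here. The interferon-stimulated genes argue against the reading of that DSS+Ta array as a control. Neither value tells whether the arrays titled DSS+AV may have received DSS alone. Eif2s3y and Xist set the controls apart from all 6 other arrays. The comparisons against control may therefore hold a difference in sex as well as in treatment.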
